A study of Homo sapiens with 120 samples.

How the data were processed

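Total RNA of HepG2 cell cultures was measured on Illumina HT-12 v4 bead arrays, 1 array per flask, and the series comprises 120 arrays. Per the labels' protocols, cells were plated at 40000 per cm2, grown for 48 h and exposed for 72 h, the particles measured 22 to 214 nm when dry, and the RNA integrity numbers were 9.8 to 10. The series text calls the flasks of a treatment biological replicates. The deposited values are probe intensity on a linear scale, which the authors made with beadarray 2.4.1 in R 2.14.0, per the series text. The background correction, the normalization and a genome build are not given in the sources used here. In the deposited intensity values every array has a median of 98.4, the values run from 52.5 to 18529, and at all but 2 ranks the sorted log2 values of the arrays lie within 0.01 of each other, as quantile normalization gives. A quantile step planned for linear values therefore had nothing to change, and the log2 of the deposited values was analysed. Such a normalization removes any difference in the total amount of RNA between groups, so changes are relative to the other genes of an array.

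Groups were taken from the labels: 8 controls and 24 groups of 8 materials at 0.3, 3 and 30 µg/mL with 4 or 5 arrays each. The letters in the titles of the controls match their replicate numbers and were not read as materials. In 1 array of material M the title gives the low dose and the characteristic 3 µg/mL, so it entered no comparison, which leaves 119 arrays. The smallest root mean square log2 difference between 2 arrays was 0.104 (median over pairs 0.276), and 0 pairs of arrays were identical. Of 48107 probes, 30113 have 1 gene symbol in the platform annotation, 8 have several and 17986 have none. By Entrez identifier 30074 probes matched the gene names used here, and 0 symbols changed. A gene was represented by its brightest probe over all arrays, chosen without regard to group, which gave 20046 genes, 6691 of them with over 1 probe. Detection p values were not used here, and no dim probe was left out except as an alternative.

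Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 1 fit over all 25 groups with no covariates, prior degrees of freedom 2.15, total 96.2), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05. Comparisons were each group against control, 30 against 0.3 µg/mL within each material, and an F test and 28 pairs among the 8 materials at 30 µg/mL. The labelled oxides were compared with limma on the 8 material means. The 33 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over all 792 tests, and again with an estimated correlation and with fry, which does not compare a list with other genes. Members past the threshold were counted over all genes and adjusted over the list alone. The lists, tests, groups and rule for named genes were fixed before the data were examined. By that rule the text names, at 30 µg/mL, the 5 largest rises and 5 largest falls among passing genes with every treated array beyond the control mean, the 10 genes that rose and the 10 that fell in the most materials, the 10 with the largest F, the 4 members of smallest p in each called list, and 10 fixed stress and liver genes. The 5 and 5 were also taken for 30 against 0.3 µg/mL in the material with the most such genes, and where no gene passed, the 3 with the smallest p. Other genes were chosen after their values were seen, and the text says so.

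Comparisons with control share the same 8 controls, so their correlation was set beside 200 draws of simulated unchanged groups and beside 35 splits of the controls. The fit was tested on simulated data for A at 30 µg/mL against control over 20046 genes. Of 100 genes changed by 0.5 on the log2 scale 93 were called, and of 100 changed by 1 all 100 were. False calls came to 6, and 0 genes were called in an unchanged comparison. Another division of the real arrays called 946 genes for A at 30 µg/mL, so the simulated error rate need not hold for real arrays. Single values between 2 groups were compared with two-sided exact permutation tests. Alternatives were the mean of a gene's probes, every probe on its own, genes below the median level left out, quantile normalization, median centring, a replicate block, blocks of 12 arrays in the order of deposit, limma's trend and robust prior, a change of at least 1.5-fold, separate fits, and leaving out each array or material in turn. Leaving out the 9 arrays that stand apart, or giving them a term, was chosen after seeing the data. Tables were handled with version 1.17.8 of data.table, pandas 2.3.3 and numpy 2.4.6, and plots drawn with matplotlib 3.10.9 in Python 3.11.15.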

Results

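HepG2 cells, a human liver line, were exposed for 72 h to powders of titanium dioxide or cerium dioxide nanoparticles, and their total RNA was read on Illumina HT-12 bead arrays. The 119 arrays used here fall into 25 groups: 8 untreated control flasks, and 8 materials at 0.3, 3 and 30 µg/mL with 4 or 5 flasks in each group. The labels code the materials A, B, C, D, H, I, L and M. Materials A (Degussa), H (Mknano) and I (Acros) are labelled as titanium dioxide, and B and M (both Nano Amor) and C, D and L (all Alfa Aesar) as cerium dioxide. The series compares such materials from different vendors for their effect on gene expression in liver cells. It counts fewer formulations than the 8 codes, and which codes would share a formulation is not given in the sources used here, so each code was treated as a material of its own. Values are deposited intensities, already brought to 1 distribution over arrays with a median of 98.4 in every array, and 20046 genes were tested. The number of arrays per group limits the precision of each value. Changes are log2 changes ± SE of 5 treated against 8 control arrays unless another n is given, and a gene passed the test where limma's adjusted p was under 0.05.

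Some arrays differed from the rest in ways their groups do not describe. Of the 119 arrays, 9 stood apart on the first principal component, which held 40% of the variance. They were 2 of the 5 arrays of M at 30 µg/mL, 2 of the 5 of H at 30 µg/mL, and 1 each of A at 30, I at 0.3, I at 3, L at 0.3 and L at 30 µg/mL. No control was among them, and all 9 are neighbours in the order of deposit. Counts are therefore also given without these 9 arrays, an alternative chosen after seeing the data. An axis was drawn from the mean of controls 1 to 7 (set to 0) to control 8 (set to 1), which fixes the place of control 8, and controls 1 to 7 lay between -0.20 and 0.21. The changes of the materials at 30 µg/mL, computed against controls 1 to 4, were set against the difference between control 8 and controls 5 to 7, with the 9 arrays left out. Across genes, which are not independent replicates, the correlation was 0.64 for A, 0.64 for H, 0.67 for I and 0.38 for L. It was 0.26 for B, 0.23 for D, -0.18 for C and -0.26 for M. Single controls 1 to 4, each against the other 3, gave 0.00, -0.23, 0.39 and -0.13. The highest of these is about the value of L. That control is 1 flask, while L is a mean of 4 arrays, so the comparison bounds L only roughly.

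**Figure D1:**
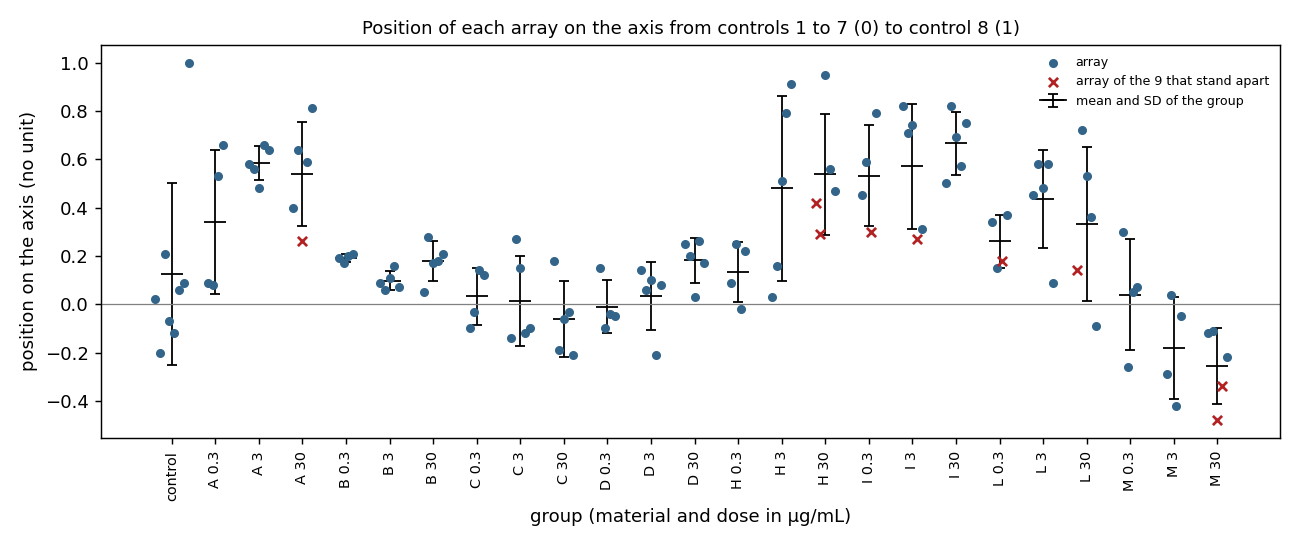
Position of each array (points) on the axis from controls 1 to 7 (0) to control 8 (1), with no unit, for the control and the 24 treated groups; bars are the group mean and SD, and crosses are the 9 arrays that stand apart. Group means of material I lie at 0.53, 0.57 and 0.67, and those of C at 0.03, 0.01 and -0.06.

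In material M at 30 µg/mL the lists of oxidative phosphorylation and ribosomal protein genes fell. LCN15, a secreted lipocalin, rose by 1.40 ± 0.13 (2.64-fold, adjusted p = 1.26e-14, probe ILMN_1803862), and was higher than the control mean in 5 of 5 arrays. The actin-bundling protein gene FSCN1 rose by 1.25 ± 0.20 (adjusted p = 1.15e-06), and ZYX, which encodes zyxin of focal adhesions, by 1.24 ± 0.23 (adjusted p = 2.11e-05). CTXN1 rose by 1.35 ± 0.21 and PHLDA1 by 1.31 ± 0.20 (adjusted p = 4.40e-07 and 5.15e-07). The falls were led by COX7B, a subunit of cytochrome c oxidase, which fell by 1.56 ± 0.25 (2.95-fold, adjusted p = 1.13e-06, probe ILMN_2184049), and COXFA4, of the same complex, which fell by 1.47 ± 0.23 (adjusted p = 7.21e-07). STOM, which encodes the membrane protein stomatin, fell 2.83-fold (SE 0.27 on the log2 scale), the signal peptidase subunit gene SEC11C by 1.49 ± 0.48 and the noncoding RNA ZFAS1 by 1.47 ± 0.26 (adjusted p = 1.35e-05, 0.021 and 1.32e-05).

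Of the 36 measured genes of oxidative phosphorylation, 15 fell and 3 rose in M at 30 µg/mL (16 and 6 when adjusted over the list alone), with a mean change of -0.29. Among them COX7A2 fell by 0.99 ± 0.09 (adjusted p = 6.99e-14), NDUFA2 by 0.64 ± 0.09 in 4 of 5 arrays (adjusted p = 1.94e-07) and COX5B by 0.46 ± 0.08 (adjusted p = 6.03e-06). Of 38 ribosomal protein genes, 17 fell and 0 rose (19 and 3 when adjusted over the list alone), with a mean change of -0.27. RPS13 fell by 0.55 ± 0.06, RPS23 by 0.77 ± 0.11, RPS27 by 0.40 ± 0.06 and RPL37 by 0.50 ± 0.09 (adjusted p = 9.02e-11, 1.85e-07, 1.65e-06 and 9.30e-06). Both lists fell against other genes in camera (adjusted p = 2.67e-05 and 5.94e-08), and did so with an estimated correlation too (adjusted p = 0.0326 and 0.0226). The list of 26 acute phase proteins, which liver cells secrete in inflammation, also fell in M (adjusted p = 0.00795, and adjusted p = 0.0973 with an estimated correlation). Of its members 5 fell and 0 rose (5 and 0 when adjusted over the list alone), among them HP, which encodes haptoglobin, by 1.40 ± 0.15 (2.64-fold, adjusted p = 6.01e-12). Also lower were the fibrinogen genes FGB, which fell by 0.76 ± 0.16, and FGG, which fell by 0.54 ± 0.15, and ITIH3, which fell by 0.31 ± 0.10 (adjusted p = 2.34e-04, 0.0059 and 0.0136).

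Proliferation genes moved the other way. Of 30 G2 and M phase genes, 16 rose and 0 fell in M at 30 µg/mL (18 and 0 when adjusted over the list alone), with a mean change of 0.35 (adjusted p = 3.19e-05, and adjusted p = 0.641 with an estimated correlation). TOP2A, which encodes a DNA topoisomerase, rose by 1.02 ± 0.20, the mitotic kinase gene PLK1 by 0.88 ± 0.18, the kinetochore protein gene CENPF by 0.77 ± 0.13 and the spindle motor gene KIF11 by 0.41 ± 0.08 (adjusted p = 5.82e-05, 1.33e-04, 2.54e-06 and 4.22e-05). Of 29 S phase genes, 12 rose and 1 fell (13 and 1 when adjusted over the list alone), with adjusted p = 0.0311 for the list and adjusted p = 0.672 with an estimated correlation. RRM2, a subunit of ribonucleotide reductase, rose by 0.59 ± 0.10 and the replication licensing gene CDT1 by 0.64 ± 0.13 (adjusted p = 3.25e-06 and 1.98e-04). MCM4 rose by 0.39 ± 0.11 and UHRF1 by 0.53 ± 0.15 (adjusted p = 0.00668 and 0.00715). Of 26 immediate early genes, 11 rose and 1 fell (12 and 2 when adjusted over the list alone), with adjusted p = 3.71e-04 and, with an estimated correlation, adjusted p = 0.26. JUND rose by 0.56 ± 0.08, FOSB by 0.33 ± 0.05 and IER3 by 0.95 ± 0.15 (adjusted p = 2.87e-08, 3.77e-07 and 1.07e-06).

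In all, 2105 genes rose and 1378 fell in M at 30 µg/mL, and chance is not excluded for this count. Without the 9 arrays, 2 of them here, 912 rose and 709 fell, 1134 of them called both times. Leaving out 1 array at a time gave 1539 genes (without replicate 3) to 4213 (without replicate 5). Without those arrays the mean change of the ribosomal protein list was -0.12 and still passed (adjusted p = 7.50e-05). The acute phase list then missed the threshold at a mean change of -0.11 (adjusted p = 0.0872), FGB at -0.33 (0.0816), FGG at -0.02 (0.935) and MCM4 at 0.22 (0.221). ITIH3 at -0.30 (0.0793) and UHRF1 at 0.45 (0.0995) missed it with changes close to those with all arrays. The change of SEC11C was then -0.41, of ZFAS1 -0.81, of STOM -0.97, of ZYX 0.67, of FSCN1 0.76, of CTXN1 0.84, of PLK1 0.56 and of FOSB 0.19, each less than with all arrays by over 1.5 times and still past the threshold.

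Material H at 30 µg/mL, with 1183 genes higher and 714 lower, shared part of its largest rises with other materials: UBR4, PRRC2A and APP rose in A, I and L as well. UBR4, a ubiquitin ligase, rose by 1.28 ± 0.20 (2.44-fold, adjusted p = 4.53e-06, probe ILMN_1699226). PRRC2A rose by 1.24 ± 0.21 and the RNA-binding ubiquitin ligase gene TRIM71 by 1.21 ± 0.18 (adjusted p = 4.05e-05 and 2.33e-06). APP, the amyloid precursor gene, rose by 1.19 ± 0.22 and the HSP90 co-chaperone gene STIP1 by 1.16 ± 0.20 (adjusted p = 8.59e-05 and 4.67e-05). The keratin gene KRT18 fell by 1.28 ± 0.25 (2.43-fold, adjusted p = 2.30e-04, probe ILMN_1803408) and CHP1 by 1.19 ± 0.30 (adjusted p = 0.00512). IMMT, which organises mitochondrial cristae, fell by 1.14 ± 0.38, RPL21P28, a pseudogene of RPL21 whose probe was not checked for cross-hybridization, by 1.12 ± 0.32 and the nucleolar GTPase gene GNL2 by 1.05 ± 0.25 (adjusted p = 0.0379, 0.0143 and 0.00288).

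Of 36 oxidative phosphorylation genes, 7 fell and 1 rose in H at 30 µg/mL (11 and 3 when adjusted over the list alone; camera adjusted p = 0.0329, and adjusted p = 0.297 with an estimated correlation). ATP5PO, ATP5F1C and SDHD fell by 0.53 ± 0.14, 0.62 ± 0.18 and 0.71 ± 0.20, while SDHC rose by 0.53 ± 0.11 (adjusted p = 0.00952, 0.0148, 0.0154 and 6.22e-04). Of 29 proteasome genes, 5 fell and 1 rose (8 and 1 when adjusted over the list alone; adjusted p = 0.0136, and adjusted p = 0.189 with an estimated correlation). PSMD12 fell by 0.49 ± 0.12, PSMC2 by 0.34 ± 0.11 and PSME2 by 0.29 ± 0.10, and PSMD3 rose by 0.32 ± 0.09 (adjusted p = 0.00354, 0.0354, 0.0358 and 0.0156). Leaving out 1 array at a time gave 590 genes (without replicate 2) to 2840 (without replicate 3). Chance is not excluded for the count in H. Without the 9 arrays, 2 of them in H, 453 genes rose and 336 fell, 460 of them called both times. The oxidative phosphorylation list then did not pass (adjusted p = 0.15), the proteasome list passed with a mean change of -0.11 (adjusted p = 0.0217), and of these members SDHC alone did (adjusted p = 0.00635). ATP5PO, ATP5F1C and SDHD stood at -0.12, -0.28 and -0.27, PSMD12, PSMC2 and PSME2 at -0.22, -0.22 and -0.03, and PSMD3 at 0.14. IMMT then stood at -0.07 (adjusted p = 0.798). CHP1 at -0.39, GNL2 at -0.46, PRRC2A at 0.77 and STIP1 at 0.71 were still past the threshold (adjusted p = 0.0268, 0.00411, 0.00519 and 0.00262).

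In material A at 30 µg/mL, 1234 genes were higher and 472 lower than in the controls. UBR4 rose by 1.22 ± 0.20 (2.34-fold, adjusted p = 5.88e-06), CHPF, which acts in chondroitin synthesis, by 1.19 ± 0.21 (adjusted p = 2.34e-05) and HYOU1, a chaperone of the endoplasmic reticulum, by 1.12 ± 0.23 (adjusted p = 3.89e-04). PRRC2A and CLUH, the latter a binder of messages for mitochondrial proteins, both rose by 1.05, with SE of 0.21 and 0.16 (adjusted p = 3.32e-04 and 1.52e-06). The small nucleolar RNA SNORD13 fell by 1.38 ± 0.29, the lysozyme gene LYZ by 1.35 ± 0.24 (2.55-fold) and the autophagy protease gene ATG4B by 1.09 ± 0.25 (adjusted p = 4.26e-04, 3.71e-05 and 0.00149). EIF3CL fell by 1.04 ± 0.21 and NUCKS1 by 1.00 ± 0.24 (adjusted p = 2.20e-04 and 0.00222). The level of EIF3CL in A, 6.65 on the log2 scale, lies close to the array median, where signal over background limits the reading. The inducible heat shock gene HSPA1A fell by 0.78 ± 0.20 (adjusted p = 0.00588).

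Ribosomal protein genes fell as a list in A at 30 µg/mL, with a mean change of -0.15 (adjusted p = 0.00555, and adjusted p = 0.271 with an estimated correlation). 2 of its 38 members fell and 0 rose (1 and 0 when adjusted over the list alone): RPL22 by 0.46 ± 0.11 and RPL13 by 0.60 ± 0.20 (adjusted p = 0.00147 and 0.0446), while RPLP1 stood at -0.52 ± 0.23 and RPS2 at -0.21 ± 0.09 (both adjusted p = 0.186). The G2 and M phase list fell too, by a mean of 0.18 in 3 of 5 arrays (adjusted p = 0.00498, and adjusted p = 0.723 with an estimated correlation), with 0 of 30 members past the threshold, also when adjusted over the list alone. Its members with the smallest p were NUSAP1 at -0.32 ± 0.12, CDK1 at -0.44 ± 0.18, NEK2 at -0.34 ± 0.14 and PTTG1 at -0.31 ± 0.14 (adjusted p = 0.0841, 0.141, 0.144 and 0.198). Without replicate 3, the array of this group that stands apart, 853 genes passed, and without all 9 arrays 1943 did, 1257 of them called both times. Both lists then missed the threshold, at mean changes of -0.08 and -0.12 (adjusted p = 0.0533 and 0.0962), RPL13 stood at -0.27 (adjusted p = 0.0815), and NUCKS1 passed at -0.66 (adjusted p = 0.00701).

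In material I at 30 µg/mL, 525 genes were higher and 261 lower than in the controls, and the 3 largest of the changes named here were falls. RPL21P28 fell by 2.04 ± 0.32 (4.12-fold, adjusted p = 1.84e-05), RPL21 by 1.54 ± 0.28 (adjusted p = 2.59e-04) and KRT18 by 1.75 ± 0.25 (3.37-fold, adjusted p = 5.53e-06), each below the control mean in 5 of 5 arrays. OSTC, a subunit of the oligosaccharyltransferase, fell by 1.22 ± 0.28 and RPS7 by 1.12 ± 0.26 (adjusted p = 0.00343 and 0.00416). The laminin gene LAMB2 rose by 1.03 ± 0.25, UBR4 by 1.01 ± 0.20 and the tyrosine kinase gene SRC by 0.95 ± 0.14 (adjusted p = 0.00507, 7.44e-04 and 9.74e-06). The nuclear pore gene NUP210 rose by 0.87 ± 0.13 and the recombinase gene DMC1 by 0.86 ± 0.24 (adjusted p = 7.70e-06 and 0.0231). Of 30 G2 and M phase genes, 2 fell and 0 rose (10 and 0 when adjusted over the list alone), with a mean change of -0.31 (adjusted p = 2.19e-11, and adjusted p = 0.425 with an estimated correlation). These were PTTG1, which encodes securin, by 0.59 ± 0.14, and the cyclin gene CCNA2 by 0.66 ± 0.18 (adjusted p = 0.00507 and 0.0167), while CDK1 and HMMR stood at -0.57 ± 0.18 and -0.47 ± 0.15 (adjusted p = 0.0565 and 0.0569). The S phase list fell by a mean of 0.08 (adjusted p = 0.0185, and adjusted p = 0.662 with an estimated correlation) with 0 of 29 members past the threshold, also when adjusted over the list alone. PRIM1, RRM2, SLBP and RFC3 had its smallest p, at -0.21 ± 0.07, -0.27 ± 0.10, -0.22 ± 0.08 and -0.17 ± 0.08 (adjusted p = 0.0723, 0.11, 0.112 and 0.237). Without the 9 arrays, none in this group, 786 became 2054 genes at the same changes (KRT18 at -1.75), as only the spread pooled over groups differs. Leaving out 1 array at a time gave 502 (without its replicate 1) to 1209 (without control 8).

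In material L at 30 µg/mL, 1049 genes were higher and 334 lower than in the controls. PRRC2A rose by 1.13 ± 0.21, PLXNB2, a semaphorin receptor gene, by 1.06 ± 0.24, and SPRY4, an inhibitor of growth factor signalling, by 0.95 ± 0.15 (adjusted p = 2.08e-04, 0.0015 and 2.00e-05). TMEM184B rose by 0.91 ± 0.16 and STIP1 by 0.90 ± 0.20 (adjusted p = 7.53e-05 and 0.00175). SNORD13 fell by 1.64 ± 0.29, LYZ by 1.38 ± 0.24 (2.61-fold) and NUCKS1 by 1.09 ± 0.24 (adjusted p = 8.06e-05, 7.53e-05 and 0.0012), as they did in A. The histamine methyltransferase gene HNMT fell by 0.93 ± 0.23 and the histone gene H2AC6 by 0.89 ± 0.21 (adjusted p = 0.00471 and 0.00209). Of 30 G2 and M phase genes, 7 rose and 0 fell (7 and 0 when adjusted over the list alone), with a mean change of 0.20 (adjusted p = 0.0069, and adjusted p = 0.733 with an estimated correlation). TOP2A rose by 0.76 ± 0.20, CENPF by 0.50 ± 0.13, TPX2 by 0.45 ± 0.12 and MKI67 by 0.20 ± 0.05 (adjusted p = 0.00682, 0.00615, 0.00964 and 0.00441). MKI67, at a log2 level of 6.56 in the controls, lies close to the array median, where signal over background limits the reading. The ribosomal protein list fell by a mean of 0.17 (adjusted p = 1.95e-04, and adjusted p = 0.109 with an estimated correlation), where replicate 1 stood at -0.51 and the other arrays at -0.09 on average. 2 of its 38 members fell and 0 rose (2 and 0 when adjusted over the list alone), RPS2 by 0.35 ± 0.09 and RPL22 by 0.33 ± 0.11 (adjusted p = 0.00868 and 0.0399), while RPL3 stood at -0.26 ± 0.09 and RPLP1 at -0.56 ± 0.23 (adjusted p = 0.0747 and 0.161). Without replicate 1, which stands apart, 466 genes passed, and without all 9 arrays 1330 did, 909 of them called both times. RPL22 and these 4 G2 and M phase genes then missed the threshold, RPL22 at -0.18 and TOP2A at 0.45 with smaller changes (adjusted p = 0.322 and 0.13). CENPF at 0.39, TPX2 at 0.38 and MKI67 at 0.14 lay closer to their values with all arrays (adjusted p = 0.0522, 0.0521 and 0.0722). PLXNB2 at 0.69 and STIP1 at 0.57 passed (adjusted p = 2.17e-04 and 0.00406).

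In material B at 30 µg/mL fewer genes changed, with 110 higher and 39 lower. The glucuronosyltransferase genes UGT2B11 and UGT2B10 rose by 0.71 ± 0.18 (1.63-fold) and 0.61 ± 0.16, and HIGD1A, of the mitochondrial inner membrane, by 0.69 ± 0.17 (adjusted p = 0.029, 0.0332 and 0.0309). TIA1, an RNA-binding protein of stress granules, rose by 0.65 ± 0.14 and LPAR6, a receptor for lysophosphatidic acid, by 0.63 ± 0.16 (adjusted p = 0.0116 and 0.0332). The small noncoding RNA SNAR-A1 fell by 0.75 ± 0.19, CXXC5 and the histone gene H4C3 by 0.63 with SE of 0.15 and 0.13, the pepsinogen gene PGC by 0.61 ± 0.14 and TGFBRAP1 by 0.58 ± 0.15 (adjusted p = 0.0355, 0.0174, 0.0115, 0.0168 and 0.044). Hepatocyte secreted proteins fell as a list, with a mean change of -0.14 in 5 of 5 arrays (adjusted p = 0.00728, and adjusted p = 0.342 with an estimated correlation). None of its 29 members passed over all genes and 2 fell when adjusted over the list alone. APOE stood at -0.38 ± 0.11, APOC3 at -0.61 ± 0.19, APOC1 at -0.38 ± 0.14 and the clotting factor gene F10 at -0.43 ± 0.17 (adjusted p = 0.0846, 0.107, 0.222 and 0.244). The count was 8 without B replicate 5 and 306 without control 3. Without the 9 arrays, none in this group, it was 855, at the same changes.

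In materials C and D at 30 µg/mL, 13 and 3 genes changed. In C the phosphodiesterase gene GDE1 rose by 0.43 ± 0.08 (1.35-fold, adjusted p = 0.00283), the troponin gene TNNI2 by 0.33 ± 0.06 (adjusted p = 7.58e-04) and the U4 small nuclear RNA RNU4-2 by 0.55 ± 0.12 (adjusted p = 0.029). NARF and GCNT3 both rose by 0.38 ± 0.08 (adjusted p = 0.029 and 0.0374). The nuclear receptor coactivator gene NCOA6 fell by 0.48 ± 0.11, PROSER1 by 0.45 ± 0.09, ANKRD11 by 0.40 ± 0.08, AKAP17A by 0.39 ± 0.07 and ZNF594 by 0.22 ± 0.05 (adjusted p = 0.029, 0.00714, 0.029, 8.97e-04 and 0.0429). Antioxidant and glutathione enzymes rose as a list in C, by a mean of 0.09 (adjusted p = 0.0158, and adjusted p = 0.238 with an estimated correlation), with 0 of 27 members past the threshold and 3 that rose when adjusted over the list alone. TXN2 stood at 0.23 ± 0.06, MGST3 at 0.27 ± 0.09, MGST1 at 0.36 ± 0.12 and GSTM1 at 0.29 ± 0.11 (adjusted p = 0.178, 0.276, 0.279 and 0.372). Immediate early genes fell as a list in C, by a mean of 0.10 (adjusted p = 0.0311, and adjusted p = 0.519 with an estimated correlation), with 0 of 26 past the threshold and 2 that fell when adjusted over the list alone. Replicate 5 stood at -0.37 on this list and the other arrays at -0.03 on average. EGR1 stood at -0.61 ± 0.17, SPRY4 at -0.46 ± 0.15, EGR3 at 0.09 ± 0.03 and IER3 at -0.34 ± 0.15 (adjusted p = 0.135, 0.282, 0.337 and 0.478). In D, CCDC9B rose by 0.47 ± 0.07 (1.39-fold, adjusted p = 2.95e-05), PRRG4 by 0.34 ± 0.07 (adjusted p = 0.0309) and ZNF526 by 0.31 ± 0.06 (adjusted p = 0.00281). The G2 and M phase list fell in D by a mean of 0.23 in 5 of 5 arrays (adjusted p = 1.05e-11, and adjusted p = 0.414 with an estimated correlation), with 0 of 30 members past the threshold, also when adjusted over the list alone. TOP2A, HMMR, CCNA2 and TPX2 stood at -0.53 ± 0.20, -0.39 ± 0.15, -0.44 ± 0.18 and -0.29 ± 0.12 (adjusted p = 0.549, 0.668, 0.768 and 0.812). Without the 9 arrays, none in these groups, 293 genes passed in C and 87 in D, at the same changes. Leaving out 1 array at a time moved C between 4 genes (without control 8) and 77 (without control 2), and D between 1 (without its replicate 5) and 30 (without its replicate 3).

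Of 10 stress and liver genes fixed in advance, 5 calls were made over the 8 materials at 30 µg/mL. In M the metallothionein gene MT2A rose by 0.71 ± 0.17, the cell cycle inhibitor gene CDKN1A by 0.59 ± 0.14 and the heme oxygenase gene HMOX1 by 0.38 ± 0.12 (adjusted p = 0.00124, 0.00126 and 0.015). HMGCS1, of cholesterol synthesis, fell in M by 0.35 ± 0.10 (adjusted p = 0.00913). Without the 9 arrays, 2 of them in M at 30 µg/mL, HMOX1 stood at 0.09 in M (adjusted p = 0.699). CDKN1A then stood at 0.33 (adjusted p = 0.0517) and MT2A at 0.44 (adjusted p = 0.0121). Besides these 4 and HSPA1A in A, none of the 10 genes HMOX1, NQO1, GCLM, MT2A, HSPA1A, DDIT3, CDKN1A, HMGCS1, ALB and CYP1A1 passed the test in any of the 8 materials. GCLM, which encodes a subunit of the enzyme that starts glutathione synthesis, came closest, at -0.38 ± 0.12 in I (adjusted p = 0.0528). Without those 9 arrays GCLM passed in I (adjusted p = 0.00175), and so did CDKN1A in H, at -0.53 (adjusted p = 0.00254) against -0.20 with all arrays. The probe of the albumin gene ALB lies close to the highest value of the arrays (control mean 14.02 ± 0.08) and that of CYP1A1, an aryl hydrocarbon receptor target, close to their median (6.65 ± 0.04, log2 level, SD, n = 8), so neither can show a lack of change.

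At the lower doses, 814 to 2446 genes changed in materials I and L, and 35 to 880 in A. The genes named here for these doses were chosen after their values were seen. More genes changed in L at 0.3 than at 30 µg/mL, with 1698 higher and 748 lower. PRRC2A rose by 1.43 ± 0.23, PLXNB2 by 1.37 ± 0.25, the liver transcription factor gene CEBPA by 1.33 ± 0.18 and SPRY4 by 1.29 ± 0.17 (n = 4, adjusted p = 2.50e-06, 3.67e-05, 5.93e-08 and 2.01e-08). LYZ fell by 1.75 ± 0.26, SNORD13 by 1.54 ± 0.31 and H2AC6 by 1.38 ± 0.22 (adjusted p = 4.47e-07, 1.40e-04 and 2.03e-06). In L at 3 µg/mL 814 genes changed, and again SPRY4 (0.96 ± 0.15) and CEBPA (0.82 ± 0.17) rose while SNORD13 fell by 1.82 ± 0.29 (adjusted p = 2.44e-05, 9.08e-04 and 2.00e-05). In I, 1117 genes changed at 0.3 and 1547 at 3 µg/mL. KRT18 fell there, with changes of -1.64 ± 0.27 and -1.62 ± 0.25, and RPL21P28, with -1.73 ± 0.34 and -1.71 ± 0.32 (adjusted p = 3.34e-05, 6.26e-06, 5.01e-04 and 1.45e-04). CHPF rose by 1.13 ± 0.22 and 1.12 ± 0.21 (adjusted p = 4.77e-04 and 1.30e-04). In A, 35 genes changed at 0.3 and 880 at 3 µg/mL. At 3 µg/mL UBR4 rose by 1.07 ± 0.20, the dynein gene DYNC1H1 by 1.05 ± 0.17 and the immediate early gene EGR1 by 1.03 ± 0.17 (adjusted p = 1.31e-04, 1.40e-05 and 1.27e-05). At 0.3 µg/mL the hexokinase gene HK2 rose by 0.69 ± 0.14 and HSPA1B fell by 0.71 ± 0.15 (n = 4, adjusted p = 0.00798 and 0.0246). With the 9 arrays left out, 1 of which is in each of L at 0.3, I at 0.3 and I at 3 µg/mL, the counts at 0.3 and 3 µg/mL were 3362 and 2070 for L, 954 and 1964 for I, and 270 and 2079 for A. A at 0.3 µg/mL moved between 0 genes without its replicate 4 (limma, 1487 at an unadjusted p under 0.05 with all arrays) and 240 without its replicate 2, and I at 0.3 µg/mL came to 282 without its replicate 3. I at 3 µg/mL had 809 genes without its replicate 4, and L at 3 µg/mL 360 without its replicate 1 and 1347 without its replicate 5.

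**Figure D2:**
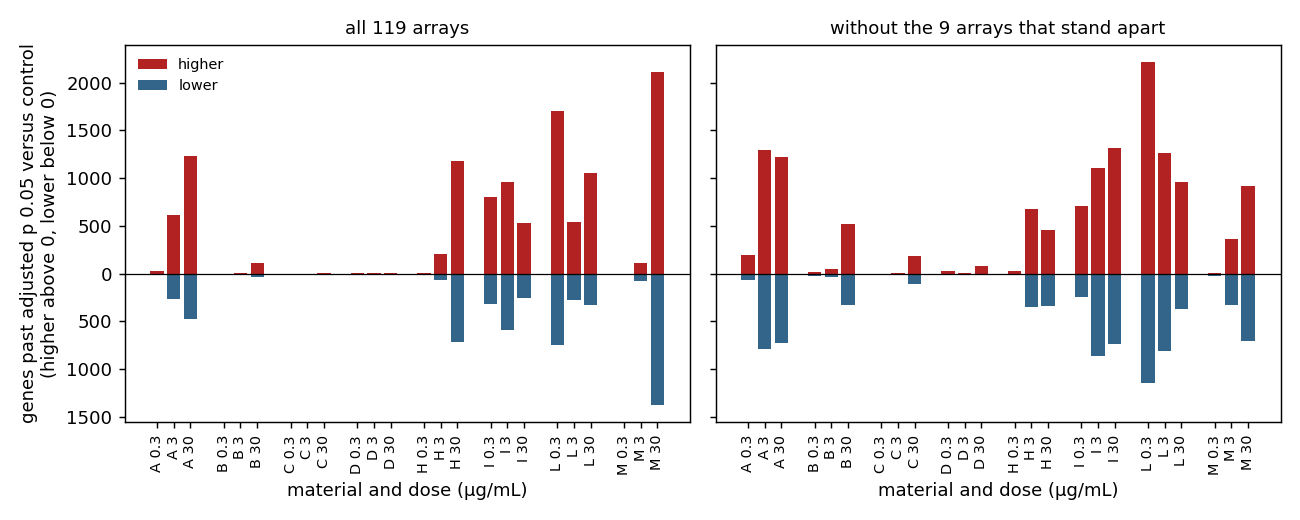
Genes past the threshold against control for each material and dose (µg/mL), genes that rose drawn above 0 and genes that fell drawn below 0, over all 119 arrays (left) and without the 9 arrays that stand apart (right). With all arrays M rises from 0 genes at 0.3 to 3483 at 30 µg/mL, and L has 2446 at 0.3 and 1383 at 30 µg/mL.

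Few genes changed in materials H, M, B, C and D at 0.3 µg/mL. In M 0 changed at 0.3 µg/mL, with 1032 at an unadjusted p under 0.05 in limma, and 192 at 3 µg/mL. There the aldo-keto reductase gene AKR1B10 rose by 1.14 ± 0.23 and the mitotic genes AURKB by 1.01 ± 0.23 and UBE2C by 0.97 ± 0.23 (n = 4, adjusted p = 0.00256, 0.00852 and 0.0157). STOM fell by 1.20 ± 0.29, the fatty acid ligase gene ACSL5 by 0.93 ± 0.16 and the chaperone gene HSPA5 by 0.78 ± 0.12 (n = 4, adjusted p = 0.0135, 2.33e-04 and 4.31e-05). In H 274 genes changed at 3 µg/mL, with SRC higher by 0.74 ± 0.14 and the calcineurin subunit gene PPP3R1 lower, at -0.75 ± 0.15 (adjusted p = 0.00269 and 0.00354). At 0.3 µg/mL 3 changed in H: ADH6 and TESK2 rose by 0.51 ± 0.10 and 0.32 ± 0.06, and the acute phase gene SERPINA3 fell by 0.29 ± 0.06 (n = 4, adjusted p = 0.0165, 0.0161 and 0.0203). In D 4 genes changed at 0.3 µg/mL, with MRPL41, ODAM, TMPRSS3 and FAM169BP higher by 0.53 ± 0.11, 0.52 ± 0.10, 0.27 ± 0.05 and 0.13 ± 0.03 (n = 4, adjusted p = 0.0497, 0.012, 0.0389 and 0.0497). FAM169BP, at a log2 level of 6.62 there, lies close to the array median, where signal over background limits the reading. At 3 µg/mL ODAM, higher by 0.48 ± 0.09, was the gene that changed in D (adjusted p = 0.0117). In C limma called 0 genes at 0.3 µg/mL, with 566 at an unadjusted p under 0.05, and at 3 µg/mL AKAP17A, which fell by 0.34 ± 0.07 (adjusted p = 0.0364). In B it called 0 genes at 0.3 µg/mL, with 1055 at an unadjusted p under 0.05, and 3 at 3 µg/mL: KCNMB3 and ARRDC3 rose by 0.44 ± 0.09 and 0.25 ± 0.04 and DCAF7 fell by 0.39 ± 0.08 (adjusted p = 0.0296, 0.00329 and 0.0378). With the 9 arrays left out the counts at 0.3 and 3 µg/mL were 34 and 690 for M, 39 and 1018 for H, 32 and 8 for D, 0 and 4 for C, and 40 and 89 for B. H at 3 µg/mL moved between 20 genes without its replicate 3 and 603 without its replicate 1, and M at 3 µg/mL between 74 without its replicate 3 and 298 without control 5. With the replicate numbers as a block M at 3 µg/mL had 61 genes, and with blocks in the order of deposit 520.

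The 2 doses of a material were also set against each other, which leaves out the shared controls. In H, 980 genes were higher and 623 lower at 30 than at 0.3 µg/mL. APP was 2.83-fold higher (SE 0.25 on the log2 scale), UBR4 by 1.44 ± 0.23 (2.72-fold), PRRC2A by 1.37 ± 0.25, TRIM71 by 1.37 ± 0.21 and CHPF by 1.33 ± 0.24 (n = 5 and 4, adjusted p = 4.00e-05, 2.06e-05, 1.07e-04, 1.57e-05 and 1.04e-04). KRT18 fell by 1.64 ± 0.29 (3.11-fold), CHP1 by 1.51 ± 0.36, RPL21P28 by 1.45 ± 0.38, H2AC6 by 1.43 ± 0.24 and the polymerase subunit gene POLR2J3 by 1.29 ± 0.27 (adjusted p = 7.08e-05, 0.00272, 0.00685, 4.00e-05 and 8.46e-04). In M, 1099 genes were higher and 426 lower at 30 µg/mL. Of 100 divisions of these arrays of M, the real one included, 8 gave as many genes. Chance is not excluded for M or H. A fit of the 2 groups alone called 293 genes in H and 0 in M. Of genes chosen after their values were seen, LCN15 was higher by 1.42 ± 0.15, the transglutaminase gene TGM2 by 1.15 ± 0.19 and the adhesion molecule gene ESAM by 1.20 ± 0.25 (adjusted p = 1.99e-11, 3.02e-05 and 8.93e-04). HP fell by 1.57 ± 0.17 (adjusted p = 1.99e-10). Between the doses 5 genes differed in A, 3 in L, and 1 each in C and I. In A the stress-induced gene DDIT4 rose by 0.84 ± 0.18, and ZNF17, ZNF526 and ZNF841 by 0.34 ± 0.06, 0.34 ± 0.07 and 0.27 ± 0.06, while OGN fell by 0.19 ± 0.04 (adjusted p = 0.0326, 0.0112, 0.0112, 0.0467 and 0.0326). In L ALDH1L1 fell by 0.40 ± 0.07, NAT8L by 0.32 ± 0.06 and the microRNA gene MIR297 by 0.18 ± 0.04 (adjusted p = 0.00499, 0.0264 and 0.0384). OGN in A and MIR297 in L, at log2 levels of 6.52 and 6.40 at 30 µg/mL, lie close to the array median. There signal over background limits the reading. TNNI2 rose in C by 0.35 ± 0.06 and the liver transcription factor gene ONECUT1 fell in I by 0.45 ± 0.08 (adjusted p = 0.00983 and 0.00165). In B and D limma called 0 genes, with 770 and 1314 at an unadjusted p under 0.05. Without the 9 arrays 1105 genes differed in H, 333 in M, 24 in L, 8 in D and 1 each in A, C and I. Leaving out 1 array at a time gave 739 (without replicate 2 at 30 µg/mL) to 2493 genes (without replicate 3) in H and 337 (without replicate 3) to 2355 (without replicate 5) in M. In the fit without the 9 arrays DDIT4 at 0.73 (adjusted p = 0.206) and ZNF17, ZNF526 and ZNF841 at 0.28, 0.31 and 0.26 (each 0.165) in A missed the threshold. So did NAT8L at -0.29 (0.0562) and MIR297 at -0.15 (0.136) in L, and all 6 changes were close to those with all arrays. The changes of CHP1 and POLR2J3 in H then stood at -0.70 and -0.69, of PRRC2A in H at 0.91 and of ESAM in M at 0.65, all past it.

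At 30 µg/mL, 7539 of the 20046 genes (37.6%) differed among the 8 materials by limma's F test, and 7982 did without the 9 arrays. SPINK1, a trypsin inhibitor gene, led the ranking (F = 31.1, adjusted p = 8.09e-18), at 9.75 ± 0.22 in L and 7.96 ± 0.18 in M against 9.32 ± 0.42 in controls (log2 level, SD, n = 5, 5 and 8). LCN15 (F = 30.5) and PDLIM7, which encodes a cytoskeletal adaptor (F = 24.3), were highest in M, and COMMD3 (F = 23.3) was lowest there (adjusted p = 8.09e-18, 6.65e-15 and 1.63e-14). MAT2A, which makes S-adenosylmethionine, ranged over 1.43 between A and M, the splicing factor gene SNRPG over 1.28 between L and M, and RPL34 over 1.79 between H and M (each adjusted p = 1.93e-14). PKD1 stood at 0.84, 0.83, 0.68 and 0.71 against control in A, H, I and L and at -0.11 in B. The apoptosis gene BAX stood at -0.95 in I and 0.48 in M, and KRT18 at -1.75 in I and 1.12 in M, a range of 2.88 (adjusted p = 1.93e-14 for PKD1 and BAX and 2.19e-14 for KRT18). Among the 28 pairs of materials the count of differing genes ran from 29 between C and D, of 1 vendor and oxide, to 4889 between B and M, also of 1 vendor and oxide, with a median of 1434. Pairs within A, H, I and L differed in 149 (A and I) to 356 genes (H and L). In the fit without the 9 arrays the counts ran from 35 between H and I to 3824 between B and C, with 226 for C and D and 3002 for B and M, 322 for A and I and 174 for H and L. KRT18 in M then stood at 0.69 (adjusted p = 0.114).

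Across materials, 42 genes rose and 10 fell in at least 5 of the 8 at 30 µg/mL, and 0 did so in 6. Without the 9 arrays 14 rose and 5 fell in at least 5, and 1, STK36, rose in 6. APP, CLUH, the lysosomal glucosidase gene GAA, the mitochondrial RNA polymerase gene POLRMT and the kinase gene MAP3K11 rose in A, H, I, L and M, with means over the 8 materials of 0.50, 0.46, 0.40, 0.39 and 0.39 (SD over materials 0.59, 0.47, 0.33, 0.36 and 0.42). VPS18, SPHK1, MYRF and HSP90AB1 rose in those 5 as well, with means of 0.35, 0.35, 0.33 and 0.32, and STK36 rose in A, B, H, I and L with a mean of 0.36. CCNY, CCL14, TVP23C, SNORD25, MRPL30, CIDECP1, STXBP6, RPL23AP7, TCAIM and SNORA7B fell in A, H, I, L and M, with means from -0.35 for CCNY to -0.14 for SNORA7B. Without the 9 arrays APP and POLRMT passed in 5 materials, and MAP3K11, SPHK1, MRPL30 and RPL23AP7 in 2. In the other direction, 217 genes rose in at least 1 material and fell in another. Comparisons that share controls share their chance values, so an overlap between their gene sets is not independent evidence. The log2 changes of 2 materials correlated across genes with a median r of 0.28 over the 28 pairs (from -0.40 for B and C to 0.75 for A and H). The 200 simulated pairs of unchanged groups against shared controls gave a median of 0.38 (from -0.43 to 0.84 with the extreme draws at both ends left out), and 0 of the 28 pairs lay outside. Without the 9 arrays the median r was 0.08 and the simulated range 0.00 to 0.71, with 3 pairs above it and 10 below. With the controls split between the 2 materials the median r was 0.12, with 0.65 for A and H, 0.61 for A and L, 0.58 for H and L, 0.49 for A and I and -0.45 for B and C. The covariance of A and H was 0.0241 and the simulated mean 0.00265. The spread of the simulated covariances is not given here, so their mean does not test a single pair. A and H shared 619 genes that rose, where independent lists of these lengths share 72.8, and I and M shared 71 (55.1 for independent lists) with 83 genes in opposite directions.

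Between the labelled oxides at 30 µg/mL, with the material as the replicate (5 cerium against 3 titanium dioxides), limma called 0 genes, with 1371 at an unadjusted p under 0.05 and a smallest adjusted p of 0.653. The 3 genes with the smallest p did not pass: TIMP3, an inhibitor of matrix proteases, stood at 7.49 ± 0.10 in the cerium and 8.13 ± 0.14 in the titanium dioxides (log2 level, SD over materials, adjusted p = 0.653). The histone variant gene MACROH2A1 stood at 12.20 ± 0.03 and 12.04 ± 0.02, and FOXP4 at 7.14 ± 0.14 and 7.71 ± 0.08 (both adjusted p = 0.653). All 5 cerium dioxides lay on 1 side of the titanium dioxide mean for each of the 3 genes. With the 9 arrays left out limma again called 0 genes, with 1989 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0558. Leaving out material L gave 11 genes. With single arrays in place of materials as replicates, 2802 genes passed, which tests these 8 materials and not the oxides.

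Of the 33 gene lists, camera called 14 in at least 1 of the 24 comparisons, 54 calls of 792 tests, and 4 of these calls held with an estimated correlation. The G2 and M phase list was called most often. It was higher in L and M at each dose and in B at 0.3 and 3 µg/mL and C at 3 µg/mL, and lower in D and I at each dose, in H at 0.3 µg/mL and in A at 30 µg/mL. In C at 3 µg/mL it turned its direction with the replicate numbers as a block (adjusted p = 0.514). In L its mean change was 0.42 at 0.3 and 0.36 at 3 µg/mL, with 14 and 8 of 30 members higher (16 and 22 when adjusted over the list alone, adjusted p = 1.55e-09 and 4.13e-15). In I it was -0.36 and -0.31, with 7 of 30 lower at either dose (17 and 11 when adjusted over the list alone, adjusted p = 6.66e-12 and 2.05e-09). In M at 3 µg/mL it was 0.43, with 6 of 30 higher (24 when adjusted over the list alone, adjusted p = 8.96e-25, and adjusted p = 0.135 with an estimated correlation). With an estimated correlation those of L and I had adjusted p = 0.498, 0.297, 0.392 and 0.505. For B at 0.3 and 3, C at 3, D at 0.3 and 3, H at 0.3 and M at 0.3 µg/mL the list had adjusted p = 1.71e-11, 0.00202, 0.0392, 1.95e-04, 0.0366, 1.05e-11 and 0.00632, and with an estimated correlation adjusted p = 0.419, 0.686, 0.795, 0.663, 0.795, 0.414 and 0.731. In these 7 groups 0 of 30 members passed over all genes, and adjusted over the list alone 2 rose in B at 0.3, 1 rose in B at 3 and 3 fell in H at 0.3 µg/mL. The control arrays alone spanned -0.41 to 0.32 on this list, with an SD of 0.25.

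**Figure D3:**
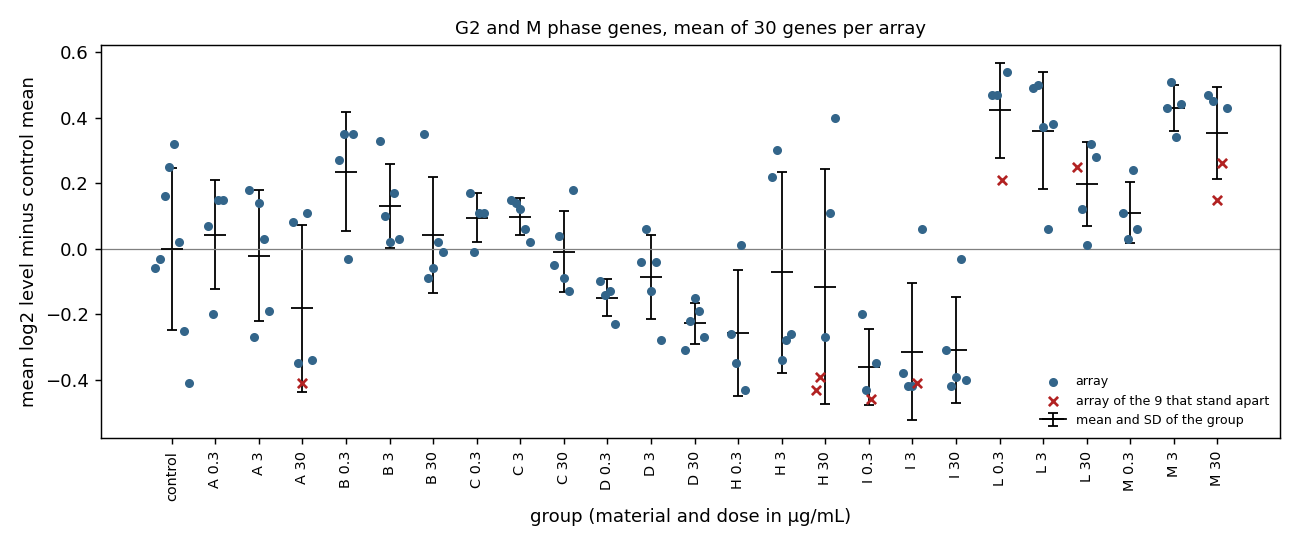
Mean log2 level of the 30 G2 and M phase genes on each array (points) minus the control mean, with the mean and SD of each group (bars) and crosses for the 9 arrays that stand apart. The controls span -0.41 to 0.32, the group means of L are 0.42, 0.36 and 0.20 and those of I are -0.36, -0.31 and -0.31.

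At the lower doses S phase genes rose in L at 0.3 µg/mL, by a mean of 0.27 with 14 of 29 members higher and 0 lower (20 and 1 when adjusted over the list alone; adjusted p = 3.92e-06, and adjusted p = 0.392 with an estimated correlation). As a list they were also higher in L at 3, M at 3, A at 0.3 and D at 3 µg/mL and lower in H at 0.3 µg/mL (adjusted p = 0.0273, 3.27e-09, 0.0192, 0.0121 and 0.00795; with an estimated correlation adjusted p = 0.671, 0.26, 0.662, 0.652 and 0.627). Of 29 members 1 rose in L and 2 in M (4 and 7 when adjusted over the list alone), and 0 passed in A, D and H, also when adjusted over the list alone. The ribosomal protein list was lower in L at 0.3 and 3 µg/mL and in M at 3 µg/mL (adjusted p = 1.84e-04, 0.00724 and 0.00893; with an estimated correlation adjusted p = 0.109, 0.297 and 0.297). Of 38 members 6, 0 and 2 fell and 1, 0 and 0 rose (7, 0 and 3 and 1, 0 and 0 when adjusted over the list alone). The proteasome list fell in H at 3 µg/mL by a mean of 0.16 with 1 of 29 members lower (3 when adjusted over the list alone; adjusted p = 5.84e-04, and adjusted p = 0.0475 with an estimated correlation). It was lower in I at 0.3 µg/mL (adjusted p = 0.0286, and adjusted p = 0.241 with an estimated correlation), with 2 members lower and 1 higher (6 and 1 when adjusted over the list alone). In B at 3 µg/mL it was higher (adjusted p = 0.00422, and adjusted p = 0.0973 with an estimated correlation), with 0 members past the threshold, also when adjusted over the list alone. The histone list rose in H at 0.3 µg/mL by a mean of 0.14 with 0 of 19 members past the threshold (3 when adjusted over the list alone; adjusted p = 0.00181, and adjusted p = 0.0475 with an estimated correlation, or 0.124 with the 9 arrays left out). It was lower in L at 0.3 and 3 µg/mL (adjusted p = 0.0464 and 0.0296; with an estimated correlation adjusted p = 0.26 and 0.213), where 7 and 2 members fell and 2 and 0 rose (9 and 4 and 2 and 0 when adjusted over the list alone). The histone list without the 9 arrays missed the threshold in L at 0.3 µg/mL with a mean change of -0.19 (adjusted p = 0.0861), against -0.18 with all arrays.

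Other lists were called at the lower doses as well. The immediate early and iron handling lists were higher in A at 3 µg/mL (adjusted p = 0.00555 and 0.0294; with an estimated correlation adjusted p = 0.382 and 0.109). Of their 26 and 19 members 4 and 2 rose and 0 fell (7 and 2 rose, and 1 and 0 fell, when adjusted over the list alone). The list of ATF4 targets, the genes of the amino acid stress response, was higher in A and L at 0.3 µg/mL (adjusted p = 0.0106 and 0.0491; with an estimated correlation adjusted p = 0.241 and 0.348), with 0 and 7 of 25 members higher (2 and 7 when adjusted over the list alone). The list of hepatocyte secreted proteins was lower in B and higher in C at 3 µg/mL (adjusted p = 0.0161 and 0.0232; with an estimated correlation adjusted p = 0.392 and 0.425). None of its 29 members passed over all genes, and 0 in B and 2 in C did when adjusted over the list alone. In M at 0.3 µg/mL the mean of the metallothionein list was lower by 0.31 and that of the oxidative phosphorylation list by 0.11 (adjusted p = 5.16e-04 and 0.0171; with an estimated correlation adjusted p = 0.297 and 0.26). None of their 9 and 36 members passed over all genes, and 3 and 0 fell when adjusted over the list alone. At 3 µg/mL the unfolded protein response list was lower by a mean of 0.15 (adjusted p = 0.0069, and adjusted p = 0.0729 with an estimated correlation), with 2 of 19 members lower (3 lower and 1 higher when adjusted over the list alone). The 19 lists without a call in any comparison were NRF2 targets, heat shock proteins, p53 targets, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation, hepatocyte regulators and metabolism, NF-kB and chemokine genes, interferon-stimulated genes, phase I xenobiotic metabolism, phase II enzymes and transporters, hypoxia and glycolysis, lysosome, autophagy, apoptosis, matrix and TGF-beta genes, housekeeping genes, and the markers of fibroblasts and endothelium and of leukocytes. Their smallest adjusted p was 0.0546, for the hepatocyte regulators in B at 30 µg/mL, and for NRF2 targets, which respond to oxidative stress, it was 0.0785 in M at 3 µg/mL.

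**Figure D4:**
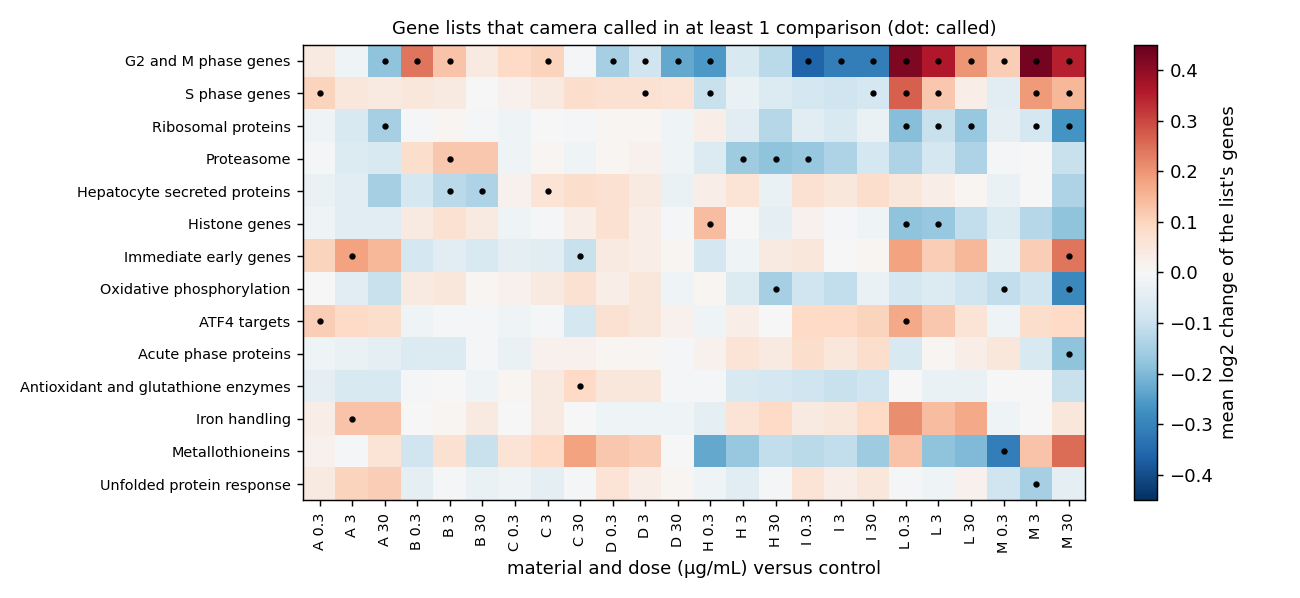
Mean log2 change of the genes of each of the 14 lists called at least once (rows) in each material and dose in µg/mL against control (columns), from blue (lower) to red (higher); dots mark calls by camera. The G2 and M phase row is red across L and M, with 0.43 in M at 3 µg/mL, and blue across I, with -0.36 at 0.3 µg/mL.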

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

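The tests of the 3 patterns weighed first were chosen only after the result was seen, as were the comparisons of divisions by where the 9 arrays that stand apart lie and the adjustment over all lists and pairs, and the other divisions of arrays at the end were chosen before it. The 9 arrays that stand apart lie next to each other in the order of deposit, the longest run of such neighbours being 9, which is consistent with arrays handled together as a candidate explanation. The material or dose of their groups as the whole cause is argued against, since the number of the 7 groups in which all arrays stand apart was 0. No label gives a batch or date, so what these arrays share beyond their place stays open.

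Along the axis to control 8, the changes of A, H, I and L at 30 µg/mL had a median correlation over genes of 0.64 with the difference between control 8 and controls 5 to 7. These 4 materials were picked because they lie along that axis, the other 4 gave -0.26 to 0.26 and single controls 1 to 4 gave -0.23 to 0.39, so whether they share a difference that untreated cultures also show stays open. A particle effect that grows with dose is argued against in I and L, which at 0.3 µg/mL already lay at 75.9 percent or more of their position at 30 µg/mL. In A that share was 56 percent, and in H the position differed between the doses with an exact permutation p of 0.0286 (two-sided, 3 against 4 arrays, the smallest p this design allows, adjusted p = 0.159 over 8 materials), and in both a particle effect and a difference of cultures cannot be told apart. An effect that does not grow over these doses was not tested.

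For the G2 and M phase genes, 87.1 percent of the variance of the 24 group means lay between materials (permutation p = 2.00e-05 with 100000 resamples). In I and L no growth with dose was seen, as the change at 0.3 µg/mL was 116 percent or more of that at 30 µg/mL. In M the exact permutation p between those doses was 0.0317 (two-sided, 5 against 4 arrays, smallest possible 0.00794, adjusted p = 0.254 over 8 materials). The SD of the controls was 1.42 times the pooled SD within treated groups, so flasks of 1 material may share a state that differs from culture to culture, which this ratio alone leaves open. Cultures and materials cannot be told apart here.

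Single arrays far from the others of their group were found in 16 of 115 sets of arrays, where chance gives about 5 percent of independent sets. These sets share arrays: 6 of the 16 come from 2 arrays that stand apart. In A at 30 µg/mL replicate 3 had UBR4 at 10.87, HYOU1 at 11.15, PRRC2A at 10.05 and NUCKS1 at 8.82 (log2 level), where the other arrays averaged 10.00, 9.44, 9.12 and 10.50. Its ribosomal protein list stood at -0.45 against -0.08, and that of L at 30 µg/mL replicate 1 at -0.51 against -0.09. UGT2B11 stood at 9.58 in B at 30 µg/mL replicate 1 (others 9.22), LAMB2 at 9.69 in I at 30 µg/mL replicate 1 (others 9.25) and LYZ at 11.50 in L at 30 µg/mL replicate 5 (others 10.14). In C at 30 µg/mL replicate 3 had RNU4-2 at 8.22 and GDE1 at 8.11 (others 7.70 and 8.44), and replicate 5 had the antioxidant list at 0.21 and the immediate early list at -0.37 (others 0.07 and -0.03). The G2 and M phase list stood at -0.03 in I at 30 µg/mL replicate 4 (others -0.38). On the control axis D at 3 µg/mL replicate 4 stood at -0.21 (others 0.10) and L at 3 µg/mL replicate 5 at 0.09 (others 0.52).

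List means at 30 µg/mL were compared between materials for the 8 pairs whose list camera had called in opposite directions, so the pairs were picked by the result. Two-sided exact permutation tests of 5 against 5 arrays were therefore adjusted over all 33 lists and 28 pairs (924 tests), of which 201 passed, 7 of these 8 pairs among them. In L the G2 and M phase list was higher than in D by 0.43 and than in I by 0.51, and the difference from A, 0.38, did not pass (exact p = 0.0317, adjusted p = 0.0975). In M it was higher than in A by 0.53, than in D by 0.58 and than in I by 0.66. Immediate early genes were higher in M than in C by 0.35, and S phase genes higher in M than in I by 0.23. Those that passed each had exact p = 0.00794 and adjusted p = 0.0365. The array of M that the labels put in no single group had its S phase list at 0.24 and its metallothionein list at 0.37, above the control ranges of -0.14 to 0.20 and -0.33 to 0.25.

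Other divisions of the same arrays into groups of the same sizes were drawn for each count of changed genes, 100 per comparison with the real one included, and these tests were chosen before the data were examined. Against control only the real division, 1 of 100, gave as many genes for A at 0.3 (35, highest other 30), A at 3 (880, highest other 237), A at 30 (1706, highest other 946), B at 30 (149, highest other 12), C at 30 (13, highest other 6), D at 30 (3, highest other 2), H at 3 (274, highest other 215), I at 0.3 (1117, highest other 362), I at 3 (1547, highest other 265), I at 30 (786, highest other 14), L at 0.3 (2446, highest other 1232), L at 3 (814, highest other 390), L at 30 (1383, highest other 1072) and M at 3 (192, highest other 73). As many or more came from 100 for B at 0.3 (0, highest other 21), 5 for B at 3 (3, highest other 14), 100 for C at 0.3 (0, highest other 2), 6 for C at 3 (1, highest other 376), 3 for D at 0.3 (4, highest other 62), 13 for D at 3 (1, highest other 7), 3 for H at 0.3 (3, highest other 7), 4 for H at 30 (1897, highest other 2711), 100 for M at 0.3 (0, highest other 80) and 3 for M at 30 (3483, highest other 3604). Between doses the numbers were 2 for A (5, highest other 5), 100 for B (0, highest other 1), 17 for C (1, highest other 3), 100 for D (0, highest other 2), 3 for H (1603, highest other 2711), 12 for I (1, highest other 2), 22 for L (3, highest other 2077) and 8 for M (1525, highest other 2697). Between pairs of materials at 30 µg/mL only 1 of 100 did for A and B (2418, highest other 813), A and C (1602, highest other 998), A and D (961, highest other 78), A and I (149, highest other 16), B and C (1808, highest other 406), B and D (448, highest other 2), B and H (3234, highest other 2811), B and I (2200, highest other 125), B and L (2861, highest other 1520), B and M (4889, highest other 3073), C and D (29, highest other 6), C and H (1769, highest other 1382), C and I (1020, highest other 175), C and L (1177, highest other 1155), C and M (2356, highest other 1297), D and H (1214, highest other 828), D and I (461, highest other 2), D and L (1266, highest other 715), D and M (3129, highest other 1839), I and L (271, highest other 57) and I and M (4103, highest other 2591). For the other pairs the numbers were 19 for A and H (257, highest other 5225), 19 for A and L (155, highest other 2543), 21 for A and M (2779, highest other 5124), 2 for H and I (320, highest other 488), 18 for H and L (356, highest other 4199), 8 for H and M (2565, highest other 5995) and 15 for L and M (1726, highest other 4514). For the counts of 0 every division gives as many by construction, so nothing is tested there. The share was under 5 percent for 18 of the 24 counts against control, 2 of the 8 between doses and 22 of the 28 between pairs. Among divisions that part the arrays that stand apart as the real one does, it was 8 percent for H and 5.56 percent for M at 30 µg/mL against control and 7.32 percent for H and 16.7 percent for M between doses. Every share computed was under 5 percent for 16 of the 24, 1 of the 8 and 22 of the 28. The share among divisions that part those arrays alike was computed only for comparisons holding at least 2 of them. No share was adjusted over the counts. Chance stays open for H and M at 30 µg/mL and between doses, and for small counts such as D at 30 µg/mL (3) and A between doses (5). Among the 8 materials 1 of 100 divisions gave as many genes (7539, highest other 4702). Between the oxides all 56 divisions of the materials give as many as the 0 that limma called (1371 at an unadjusted p under 0.05, highest other 5), again by construction. Each of the 4 divisions as large for H and the 3 as large for M at 30 µg/mL against control had both arrays that stand apart on 1 side, and the highest with those arrays on both sides were 23 and 37 genes. Divisions that call far more genes than the real one, such as 5225 against 257 for A and H, point to a structure of the arrays. Among divisions that part those arrays as the real one does, the share for A and H, A and L, A and M, H and L, H and M, L and M, and for L between doses was 2.38 percent or less.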

How the results depend on the processing

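The alternatives were chosen before the data were examined, except that leaving out the 9 arrays that stand apart, giving them a fixed term, and the block in the gene list test were chosen after seeing the data. Quantile normalization and median centring of the deposited values left every count as it was, since the values already share 1 distribution, so they test nothing here. Values below are those over 1.5 times above or below the count with all arrays, and the cause was not tested unless stated. Signal over background limits genes near the lowest values, and detection p values were not used here.

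With the mean of a gene's probes, counts were 1 for B at 0.3, 1 for B at 3, 0 for C at 3. They were 1 for D at 0.3, 9 for D at 30 and 3 for M at 0.3. Between doses the counts were 0 for I. With every probe tested on its own they were 0 for C at 3, 1 for D at 0.3, 5 for D at 30 and 1253 for I at 30, and between the doses 2 for I. With genes below the median level left out, so that fewer genes are tested, they were 57 for A at 0.3, 251 for B at 30, 5 for D at 30, 415 for H at 3 and 2 for M at 0.3. With a trend and robust prior they were 23 for A at 0.3, 1 for B at 3, 0 for C at 3, 6 for C at 30 and 1 for D at 0.3, and between the doses 2 for D. With blocks of 12 arrays in the order of deposit as a term they were 58 for A at 0.3, 8 for B at 3. They were 0 for D at 0.3, 0 for D at 3, 8 for D at 30, 0 for H at 0.3, 671 for H at 30, 738 for I at 0.3, 520 for M at 3 and 2010 for M at 30. Between the doses they were 9 for A, 634 for H and 890 for M. A change of at least 1.5-fold, a stricter criterion by construction, left 8 for A at 0.3, 139 for A at 3, 269 for A at 30, 0 for B at 3, 11 for B at 30, 0 for C at 3, 0 for C at 30. They were 0 for D at 0.3, 0 for D at 3, 0 for D at 30, 0 for H at 0.3, 36 for H at 3, 304 for H at 30, 200 for I at 0.3, 202 for I at 3, 100 for I at 30, 492 for L at 0.3, 99 for L at 3, 183 for L at 30, 44 for M at 3 and 769 for M at 30. Between doses the counts were 1 for A, 0 for C, 409 for H, 0 for I, 0 for L and 419 for M. A fit of the 2 groups alone, which has fewer arrays to estimate the spread, gave 0 for A at 0.3, 1419 for A at 3, 692 for A at 30, 0 for B at 3, 63 for B at 30, 0 for C at 3, 0 for C at 30. They were 0 for D at 0.3, 0 for D at 3, 0 for H at 0.3, 0 for H at 3, 144 for H at 30, 394 for I at 0.3, 511 for I at 3, 1196 for I at 30, 346 for L at 3, 12 for L at 30, 23 for M at 3 and 1121 for M at 30. Between the doses they were 0 for A, 112 for B, 0 for C, 364 for D, 293 for H, 0 for I, 0 for L and 0 for M, and a fit of the 8 groups at 30 µg/mL alone gave 4710 genes that differ among materials. Beside each count of 0 here limma was the test, and the counts at an unadjusted p under 0.05 with all arrays were 1487 for A at 0.3, 1318 for B at 3, 723 for C at 3, 1748 for C at 30, 1525 for D at 0.3, 886 for D at 3, 940 for D at 30, 1167 for H at 0.3 and 2183 for H at 3 µg/mL, and between doses 765 for C, 1520 for A, 1902 for I, 1021 for L and 4547 for M.

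Without the 9 arrays counts were 270 for A at 0.3, 2079 for A at 3, 40 for B at 0.3, 89 for B at 3, 855 for B at 30, 4 for C at 3, 293 for C at 30. They were 32 for D at 0.3, 8 for D at 3, 87 for D at 30, 39 for H at 0.3, 1018 for H at 3, 789 for H at 30, 2054 for I at 30, 2070 for L at 3, 34 for M at 0.3, 690 for M at 3 and 1621 for M at 30. Between doses the counts were 1 for A, 8 for D, 24 for L and 333 for M, and the median correlation of 28 pairs was 0.08. With a fixed term for those arrays counts were 185 for A at 0.3, 1827 for A at 3, 7 for B at 0.3, 69 for B at 3, 588 for B at 30, 2 for C at 3, 142 for C at 30. They were 7 for D at 0.3, 5 for D at 3, 67 for D at 30, 19 for H at 0.3, 840 for H at 3, 1252 for H at 30, 1783 for I at 30, 1801 for L at 3, 7 for M at 0.3, 530 for M at 3 and 2295 for M at 30. Between the doses they were 10 for A, 7 for D, 8 for L and 733 for M. With the array of M whose labels conflict added, M had 4 genes at 0.3 or 375 at 3 µg/mL. The oxide comparison gave 2802 genes with arrays as replicates and 11 without material L. Gene lists had 4 calls with an estimated correlation in place of 54. With fry there were 77, but of the 54 only 34 passed and 20 did not, among them the G2 and M phase list in A at 30, B at 0.3, D at 30 and H at 0.3 µg/mL (adjusted p = 0.393, 0.168, 0.176 and 0.143). Split controls gave a median correlation of 0.12.

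The replicate numbers were also used as a block. Arrays with 1 number did not deviate together (mean correlation of deviations 0.0109, against 0.00446 for other numbers, with 36.8% of 1320 pairs over 0.1), so the numbers do not pair arrays. With that block counts were 23 for A at 0.3, 13 for B at 30, 0 for C at 3, 4 for C at 30. They were 1 for D at 0.3, 30 for H at 0.3, 447 for H at 3, 3 for M at 0.3 and 61 for M at 3. Between doses the count was 8 for A, and there were 80 list calls over the 792 tests in place of 54. Of the 54 list calls 40 passed with the block in the same direction and 13 no longer did. The G2 and M phase list in C at 3 µg/mL turned its direction with the block (adjusted p = 0.514).

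Leaving out 1 array at a time gave these lowest and highest counts. Counts for A ran from 0 to 240 at 0.3, 622 to 1178 at 3 and 853 to 1877 at 30 µg/mL. Counts for B ran from 0 to 10 at 0.3, 0 to 22 at 3 and 8 to 306 at 30 µg/mL. Counts for C ran from 0 to 1 at 0.3, 0 to 2 at 3 and 4 to 77 at 30 µg/mL. Counts for D ran from 0 to 23 at 0.3, 0 to 4 at 3 and 1 to 30 at 30 µg/mL. Counts for H ran from 0 to 19 at 0.3, 20 to 603 at 3 and 590 to 2840 at 30 µg/mL. Counts for I ran from 282 to 1444 at 0.3, 809 to 1797 at 3 and 502 to 1209 at 30 µg/mL. Counts for L ran from 1982 to 2590 at 0.3, 360 to 1347 at 3 and 466 to 1954 at 30 µg/mL. Counts for M ran from 0 to 8 at 0.3, 74 to 298 at 3 and 1539 to 4213 at 30 µg/mL. Between doses the ranges were 0 to 14 for L, 0 to 0 for B, 0 to 5 for D, 0 to 1 for C, 0 to 6 for A, 1 to 5 for I, 739 to 2493 for H and 337 to 2355 for M. Genes that differ among materials ranged from 6899 to 8022.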

Other observations

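The genes below were chosen after their values were seen, and no test of an explanation is given here. At 30 µg/mL, 217 genes rose in at least 1 material and fell in at least 1 other. KRT18, a keratin of simple epithelia, rose in M by 1.12 ± 0.25 and fell in A, H and I, by 1.75 ± 0.25 in I (adjusted p = 4.66e-04 and 5.53e-06). KRT23 rose in M by 0.72 ± 0.14 and fell in H and I, by 0.70 ± 0.14 in I (adjusted p = 1.01e-04 and 0.00101). CCNA2, which encodes cyclin A2, rose in M by 0.86 ± 0.18 and fell in I by 0.66 ± 0.18 (adjusted p = 1.96e-04 and 0.0167). BAX, a promoter of apoptosis, rose in M by 0.48 ± 0.15 and fell in A, H, I and L, by 0.95 ± 0.15 in I (adjusted p = 0.0144 and 1.78e-05). MAT2A rose in A and I, by 0.74 ± 0.12 in A, and fell in M by 0.69 ± 0.12 (adjusted p = 7.39e-06 and 9.74e-06), and UGT2B11 rose in B by 0.71 ± 0.18 and fell in A, L and M, by 0.75 ± 0.18 in L (adjusted p = 0.029 and 0.00259). Without the 9 arrays, KRT18 in M stood at 0.69 (adjusted p = 0.114). KRT23, CCNA2 and BAX in M still passed (adjusted p = 0.00105, 0.0117 and 0.028).

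The small noncoding RNA SNAR-A1 rose in M by 1.10 ± 0.19 and fell in B by 0.75 ± 0.19 (adjusted p = 1.00e-05 and 0.0355). RPL34, a protein of the large ribosomal subunit, rose in H by 0.46 ± 0.14 and fell in M by 1.34 ± 0.14 (adjusted p = 0.0277 and 7.84e-12), and SPINK1 rose in L by 0.42 ± 0.13 and fell in M by 1.36 ± 0.13 (adjusted p = 0.0333 and 1.05e-13). The rise of RPL34 in H no longer passed with those arrays left out, at 0.23 (adjusted p = 0.483).

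The array of material M whose title and characteristics give different doses was used in no comparison. Its values, as deviations from a common mean of each gene, were compared with those of M across genes, which are not independent replicates. It correlated at 0.57 with M at 3 µg/mL, at 0.43 with M at 0.3 µg/mL and at 0.41 with M at 30 µg/mL. It stood at -0.15 on the control axis, at 0.32 on the G2 and M phase list, where the controls span -0.41 to 0.32, at -0.11 on the ribosomal protein list, where they span -0.09 to 0.02, and at -0.06 on the oxidative phosphorylation list, where they span -0.10 to 0.08.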
